A study of Mus musculus with 24 samples.

How the data were processed

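Liver RNA from 24 single mice was hybridised to 1-colour (Cy3) Agilent 8x60K mouse arrays, 1 array per mouse. Per the file headers, each scanner file was made with Agilent Feature Extraction 10.10.1.1 and holds, for each spot, an intensity that was background-subtracted and detrended within the array and was not normalized between arrays. The same files hold the raw mean and median spot intensity, the local background and spot quality flags. The authors also deposited a series table of 35967 probes in log2 units. Its normalization is not stated in the labels, which name limma without a version, so it was read from the values. Each of its columns correlated with the log2 median spot intensity of its own array at 0.999853 or more, across probes, with slopes between 0.982 and 1.02, and the column medians lay between 7.3834 and 7.3902. The percentiles 1 to 99 of the columns lay within 0.0413 of each other, where those of the log2 median spot intensities spread by up to 0.526. The deposited values were therefore read as log2 median intensities made nearly equal in distribution, as quantile normalization does, and the exact steps stay unknown. The series table served as an alternative, and all main values come from the scanner files.

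Of 62976 spots per array, 59305 were not controls. Control spots and spots with an outlier flag were left out, and 1 non-control spot was saturated. The processed intensity was taken to log2, the 75th percentile of the array's non-control probes was subtracted, and the spots of a probe were averaged. A probe was kept if the scanner software called it well above background on at least 6 of the 24 arrays, which left 36229 of 56605 probes. A gene was represented by its kept probe with the highest mean over all arrays. This gave 23966 genes, of which 7946 had more than 1 kept probe. Names came from a table of assembly GRCm38.p6: 15655 genes were named by accession, 1736 by symbol and 103 by synonym, and 6472 kept the array's own name. Features that the array names only by an accession or a Gm number count as genes. Probe coordinates are those of the array design, on mm9. Arrays give no counts, so the number of arrays limits the precision. Signal over background sets what can be measured: a group in which no array was well above background gives only a lower bound on a fold, for which each of its arrays was raised to at least the dimmest probe that passed on that array.

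The 4 groups of 6 mice were compared in 1 fit of group means over all 24 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with data.table (version 1.17.8). Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Intervals are 95% intervals of the limma fit, and errors of log2 fold changes are its standard errors. Replicate numbers gave no clear pairing of the mice. Deviations from the group mean correlated on average at 0.0335 between arrays of the same number in different groups. These correlations ranged from -0.174 to 0.219, and 9 of 36 pairs lay above 0.1. Between different numbers the average was -0.00674. On the same slide the averages were 0.0875 for the same number and 0.0454 for different numbers. For 8 of 24 arrays the best match in another group had their number. The fit had no block, and a block by replicate number was among the alternatives. The arrays came from 3 slides with 2 arrays of every group on each, so slide was tested as a fixed block and each comparison was repeated within each slide.

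Gene lists for 36 pathways, responses and cell types, with 430 symbols of which 408 were measured, were written before the data were examined. Each list was tested with fry (limma), whose directional p asks whether its genes move on balance one way and compares the list with no other genes, and p was adjusted over 36 lists and 4 comparisons, 144 tests. For these tests 46 missing values were filled. Camera was run as the alternative, with a preset correlation of 0.01 and with an estimated correlation. Genes were named by a rule fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, were well above background on all arrays of the higher group and had a gene symbol. It added up to 3 members of each list, called members with the largest change first and otherwise those with the lowest p, and a panel of 17 genes of sugar, lipid and fasting metabolism. In the comparisons of a sugar with water, the called genes singled out are those that kept the call with any single array left out. Not every gene that the rule names is given. A gene outside the rule is said to be chosen after its values were seen.

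The same steps were tested on simulated data with 200 changed genes among 23966 in a comparison of 6 against 6. With the change placed in the glucose group against water, 46.3% of the genes changed by 0.5 on the log2 scale were recovered, 91% of those changed by 1 and 95.5% of those changed by 2, and 7 of 162 calls were false. Alternatives covered quantile and median normalization, normexp background correction with an offset of 50, the series table, no filter and a stricter filter on dim probes, the mean of all probes of a gene, only the arrays of the groups compared, trended and robust variances, array weights, a block by replicate number, slide, other thresholds and the omission of each array. No alternative was added after the data were seen. Genes shared by 2 comparisons against the same control group were counted beside 100 simulations of unchanged groups. They were also counted under all 20 ways of giving 3 control arrays to 1 comparison and the other 3 to the other. Dixon's test at its 95% critical value for 6 samples marked arrays far from their group.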

Results

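Liver gene expression was measured in 24 male wild-type C57Bl/6J mice, 8 weeks old and kept on chow, in 4 groups of 6. Mice of 3 groups were fed and drank for 24 hours either tap water, water with 20% glucose or water with 20% fructose, and mice of the last group were fasted for 24 hours. All were killed at ZT16, 16 hours after lights on. The number of probes well above background lay between 32516 and 36272 per array, with group means of 34189.3 for water, 34620.8 for glucose, 34757.7 for fructose and 34523.5 for fasting. Correlations between arrays, across genes, ran from 0.970 to 0.995 over all pairs and were at least 0.985 within a group. The first principal component held 44.3% of the variance and set the fasted arrays, at 64.9 or more, apart from the fed arrays, at -15.3 or less. Every comparison below has 6 mice per group, and values are log2 signals relative to the array's 75th percentile.

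**Figure D1:**
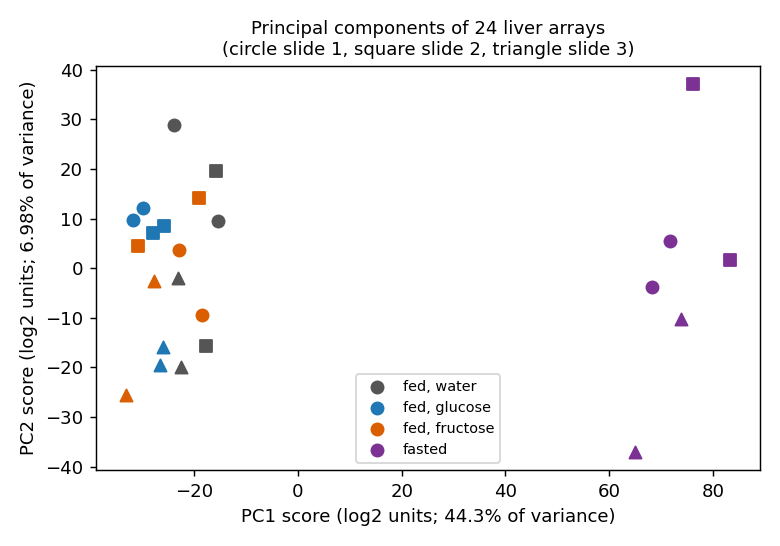
Scores of the 24 arrays on the first and second principal components (log2 units), coloured by group, with a marker for each slide. The first component, with 44.3% of the variance, separates the fasted arrays (64.9 or more) from the fed arrays (-15.3 or less).

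Fasting against feeding asks how the liver responds to 24 hours without food. In fasted mice the fatty acid hydroxylases Cyp4a14, Cyp4a10 and Cyp4a31 were 94.9-fold, 51.7-fold and 28.7-fold higher than in fed mice on water, and the lipid droplet gene Cidec was 31.9-fold higher. The hormone gene Fgf21 was 24.8-fold higher, with a log2 level of 1.78 ± 1.09 against -2.85 ± 0.83 (mean ± SD, n = 6). Pyruvate kinase, Pklr, the last enzyme of glycolysis, was 8.08-fold lower, with a log2 fold change of -3.01 ± 0.18 (SE; adjusted p = 9.8e-12). In all, 5195 genes were higher and 5016 lower, 42.6% of those tested, with 963 higher and 873 lower by at least 2-fold. The groups did not overlap in 5816 genes, 24.3% of those tested, where chance gives 0.216%. With slide as a block the counts were 5275 and 5067. Within slides 1, 2 and 3 they were 2795, 3211 and 2974 higher and 2705, 3355 and 2485 lower.

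The other largest rises by the naming rule were the metallothionein Mt2, 51.1-fold higher, thyroglobulin, Tg, at least 11.6-fold higher because no water array was above background, and Pip5k1a, 28.2-fold higher by 1 probe while the lowest of its 3 probes had a log2 fold change of -0.20. Among the largest falls were Pnpla5, at least 63.1-fold lower by its brighter probe, the transcription factor Bhlha15, at least 47.9-fold lower, Serpina4-ps1, 67.8-fold lower, Serpina9, 54.1-fold lower, and Hsd3b5, 52.9-fold lower. The other probe of Pnpla5 fell less, with a log2 fold change of -1.90. Pnpla3, a lipid droplet lipase, and Serpina12 were also lower, and with only 1 of 6 fasted arrays above background no fold is given for them. The probe of Fgf21 lies on chromosome 7 at 52869305 to 52869364 and that of Pklr on chromosome 3 between 88948907 and 88949425. All 111 called genes named by the rule kept their sign within all 3 slides, and 105 kept their call with any 1 array left out. For the largest rises and falls, here and with the sugars, that sign was fixed in advance. The rule took them from genes whose groups did not overlap.

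Genes of glucose release rose with fasting. Of 11 gluconeogenesis genes 10 were higher and 0 lower, 10 also when adjusted over the list alone (fry adjusted p = 1.83e-12, camera adjusted p = 0.0384 with an estimated correlation). They included the transaminase Got1 (3.20 ± 0.19 in log2 fold change, SE), the coactivator Ppargc1a (2.58 ± 0.27), Sds (1.87 ± 0.15), Pck1 (1.35 ± 0.20) and G6pc (1.16 ± 0.22). Of 7 fructose handling genes 4 were lower and 1 higher, 4 and 2 when adjusted over the list alone (adjusted p = 3.8e-07, adjusted p = 0.412 with an estimated correlation). Among them Tkfc was 2.89-fold lower by its brighter probe and ketohexokinase, Khk, the entry enzyme for fructose, 2.06-fold lower. The other probe of Tkfc had a log2 fold change of -0.755. Glycolysis genes went both ways, 5 higher and 4 lower of 13, and 6 and 4 when adjusted over the list alone. Their median log2 fold change was 0.005 and their mean -0.53, and the test took the sign of the mean (adjusted p = 0.000403, adjusted p = 0.956 with an estimated correlation). The carbohydrate response list had 5 higher and 5 lower of 13 (adjusted p = 0.0847), with Txnip 3.39-fold higher and Mlxipl, which encodes the sugar-sensing factor ChREBP, 2.94-fold lower by its brightest probe, while the highest of its 3 probes had a log2 fold change of 0.10.

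Fatty acid and cholesterol synthesis genes fell, while fatty acid oxidation genes and triglyceride and lipid droplet genes rose. Of 17 fatty acid synthesis genes 15 were lower and 1 higher, as when adjusted over the list alone (adjusted p = 3.84e-10, adjusted p = 0.136 with an estimated correlation). Thrsp was 22.9-fold lower, Srebf1, the regulator of the pathway, 14.4-fold, Elovl6 13.0-fold, fatty acid synthase, Fasn, 10.7-fold, and Scd1 2.37-fold. Of 24 cholesterol synthesis genes 19 were lower and 1 higher, as over the list alone (adjusted p = 9.94e-06, adjusted p = 0.384 with an estimated correlation), with a log2 fold change of -3.59 for Mvd. Among 21 targets of the fatty acid receptor PPARA, 19 were higher and 1 lower, and the counts were equal when adjusted over the list alone (adjusted p = 3.84e-10, adjusted p = 0.119 with an estimated correlation). Pdk4, a brake on glucose oxidation, was 6.40-fold higher. Fatty acid oxidation had 14 of 15 genes higher and 0 lower, also over the list alone (adjusted p = 1.56e-08, adjusted p = 0.216 with an estimated correlation), with the mitochondrial carnitine transferase Cpt1a 3.11-fold and Acadm 2.37-fold higher. Of 19 triglyceride and lipid droplet genes 11 were higher and 1 lower, also over the list alone (adjusted p = 1.9e-08, adjusted p = 0.219 with an estimated correlation), with Plin4 5.53-fold and the lipase Pnpla2 4.97-fold higher. Ketone body genes had 4 of 6 higher and 1 lower, as over the list alone (adjusted p = 0.0326, adjusted p = 0.735 with an estimated correlation). Among them Slc16a6 was 3.10-fold lower.

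Amino acid breakdown rose while protein folding genes fell. Of 20 urea cycle and amino acid breakdown genes 19 were higher and 1 lower, as over the list alone (adjusted p = 1.87e-10, adjusted p = 0.119 with an estimated correlation), with Aass 4.10-fold, histidase, Hal, 2.96-fold and the urea cycle gene Cps1 2.13-fold higher. All 18 endoplasmic reticulum chaperones were lower, also over the list alone (adjusted p = 1.75e-10, adjusted p = 0.119 with an estimated correlation), with Sdf2l1 15.0-fold, Manf 8.09-fold and Hspa5 3.26-fold lower. The ATF4 and amino acid stress list went both ways, 3 higher and 5 lower of 15, as over the list alone (adjusted p = 0.316). Asns was 4.66-fold and Trib3 4.13-fold higher and Psat1 2.14-fold lower, a call that was lost with normexp background correction. Bile acid genes also split, 4 higher and 4 lower of 12 (adjusted p = 0.91), with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 7.19-fold lower and Cyp8b1 4.80-fold higher. The clock list had 7 higher and 5 lower of 16 (adjusted p = 0.0847), with Ciart 2.92-fold and Arntl 2.56-fold higher and Per2 2.29-fold lower by its brighter probe. The other probe of Per2 had a log2 fold change of -0.29 and was not called.

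Hormone and stress targets moved as well. Glucocorticoid targets had 9 of 11 higher and 0 lower, also over the list alone (adjusted p = 5.42e-08, adjusted p = 0.176 with an estimated correlation), with the metallothionein Mt1 22.8-fold and the cell cycle inhibitor Cdkn1a 13.1-fold higher. Autophagy and lysosome genes had 10 of 13 higher and 1 lower, also over the list alone (adjusted p = 1.75e-10, adjusted p = 0.119 with an estimated correlation), with Gabarapl1 2.31-fold higher. In the insulin and growth hormone list 6 of 11 were higher and 3 lower, 7 and 3 over the list alone (adjusted p = 0.000508, adjusted p = 0.66 with an estimated correlation), with Igfbp1 12.9-fold and Irs2 3.83-fold higher. Xenobiotic genes had 6 of 11 higher and 3 lower, as over the list alone (adjusted p = 0.0235, adjusted p = 0.735 with an estimated correlation), with Cyp2b10 5.14-fold higher and Cyp2c55 4.16-fold lower. NRF2 targets had 4 of 8 higher and 1 lower, 5 and 3 over the list alone (adjusted p = 0.0235, adjusted p = 0.814 with an estimated correlation), with Nqo1 2.27-fold higher. Interferon genes had 8 of 14 lower and 2 higher, 10 and 2 over the list alone (adjusted p = 0.00472, adjusted p = 0.663 with an estimated correlation), with Cxcl10 3.23-fold lower. Cell cycle genes had 10 of 13 lower and 0 higher, as over the list alone (adjusted p = 0.00103, adjusted p = 0.49 with an estimated correlation), with Ccnd1 4.04-fold lower. Male-biased genes had 5 of 11 lower and 2 higher, as over the list alone (adjusted p = 4.89e-05, adjusted p = 0.49 with an estimated correlation), with Slco1a1 4.09-fold lower. Acute phase genes had 3 higher and 1 lower of 15 (adjusted p = 0.479).

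Among cell type markers, periportal hepatocyte genes had 8 of 10 higher and 2 lower, as over the list alone (adjusted p = 1.95e-08, adjusted p = 0.276 with an estimated correlation), while pericentral genes had 2 higher and 3 lower of 10 (adjusted p = 0.778), with Cyp1a2 3.52-fold lower. Of the periportal genes, Hal, Sds, Gls2, Ass1, Arg1 and Cps1 are also in the urea cycle and amino acid breakdown list. Pck1 is also in the gluconeogenesis list, so the periportal result largely repeats those lists. Over all genes 42.6% were called with fasting and fry compares a list with no other genes, so marker counts are to be read against that share. Stellate cell markers had 4 of 11 lower and 1 higher, 5 and 1 over the list alone (adjusted p = 0.0125, adjusted p = 0.741 with an estimated correlation), with the collagen gene Col3a1 3.60-fold lower. Cholangiocyte markers had 4 of 8 lower and 0 higher, as over the list alone (adjusted p = 0.0356, adjusted p = 0.724 with an estimated correlation). Adipocyte markers had 2 of 6 higher and 0 lower, as over the list alone (adjusted p = 0.0134, adjusted p = 0.717 with an estimated correlation). These were Adipoq, with only 1 of 6 water arrays above background, and Fabp4, 1.33-fold higher. With the strict filter on dim probes the list's median was -0.14 and the call was lost. Endothelial markers had 3 higher and 4 lower of 10 (adjusted p = 0.753), Lyve1 being 2.51-fold higher and Dnase1l3 1.60-fold lower. Markers of Kupffer cells (adjusted p = 0.181), lymphocytes (0.115), neutrophils (0.261), red cells (0.984), pancreatic acinar cells (0.163) and skeletal muscle (0.677) did not pass the test as lists. Of the 23 lists called with fasting, 21 had medians of the same sign in all 3 slides, the exceptions being male-biased genes (0.04, -0.89 and -0.09) and stellate markers (-0.24, 0.02 and -0.10). The 21 include glycolysis, called as lower, whose slide medians (0.10, 0.01 and 0.12) lie against its called direction. With any 1 array left out 18 of the 23 kept their call. Over 30 alternative settings, single arrays left out included, the ketone body list lost its call in 19, cholangiocyte markers in 16 and xenobiotic genes in 10.

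**Figure D2:**
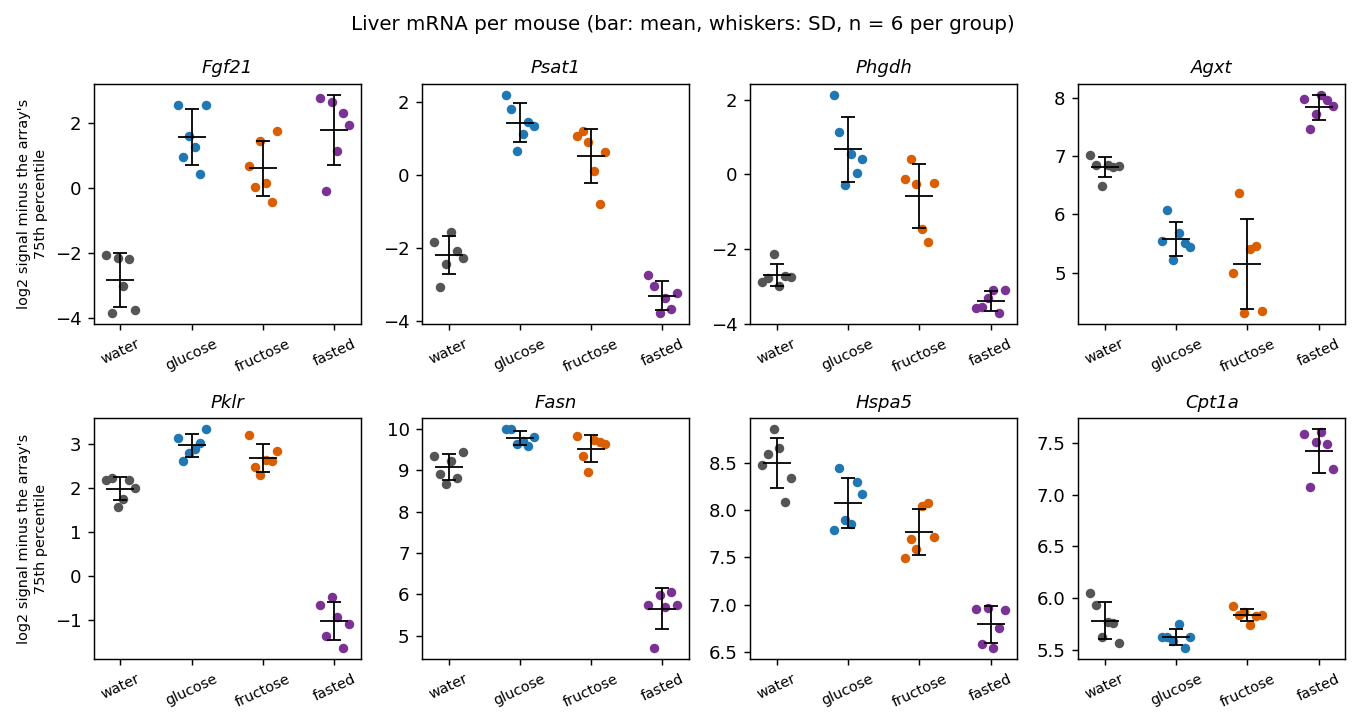
Log2 signal minus the array's 75th percentile for 8 genes, with a point per mouse, the mean as a bar and the SD as whiskers (n = 6 per group). Fgf21 is high in both sugar groups and in fasted mice, at 1.56, 0.60 and 1.78 against -2.85 on water, while Fasn is 10.7-fold lower in fasted mice than on water.

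Glucose in the drinking water asks what a sugar load adds to a fed liver. Fgf21 was 21.2-fold higher than on water, with a log2 level of 1.56 ± 0.86 (SD, n = 6; adjusted p = 2.41e-05). The serine synthesis genes Psat1 and Phgdh were 12.3-fold and 10.3-fold higher, with log2 fold changes of 3.63 ± 0.31 and 3.36 ± 0.35 (SE), and Fut1 was at least 7.56-fold higher because no water array was above background. The stress gene Nupr1 was 3.60-fold higher by its brighter probe while the other had a log2 fold change of -0.12, and Aldh1l2 was higher too, with only 1 of 6 water arrays above background. Agxt, which breaks down glyoxylate, was 2.35-fold lower, Dcxr 1.83-fold lower, Dct 2.62-fold lower by 1 of its 2 probes while the other had a log2 fold change of 0.02, and Cabp4 2.48-fold lower. In all, 98 genes were higher and 101 lower, 32 and 7 of them by at least 2-fold. With any 1 array left out there were fewer, from 54 (without fed_glucose replicate 1 or fed_water replicate 4) to 87 higher and from 46 (without fed_water replicate 5) to 85 lower. Some other settings called more genes, most of all array weights, as listed in the part on processing. The groups did not overlap in 565 genes, 2.36% of those tested, where chance gives 0.216%. With slide as a block the counts were 96 and 89. Within slides 1, 2 and 3, where 2 arrays met 2, they were 2, 0 and 36 higher and 0, 0 and 5 lower. All 35 called genes named by the rule kept their sign in all 3 slides, and 23 kept the call with any 1 array left out. The genes given here as higher or lower with glucose were chosen from those 23, so their kept calls are no further support.

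With glucose 4 lists of sugar use and fat synthesis passed the test as higher, each with fewer than 1 in 3 of its genes called. The carbohydrate response list had 3 of 13 higher and 0 lower, 6 and 0 over the list alone (adjusted p = 0.000508, adjusted p = 0.041 with an estimated correlation). Pklr was 1.98-fold higher (0.98 ± 0.18 in log2, SE; adjusted p = 0.0081), while Txnip had a log2 fold change of 0.25 (adjusted p = 0.648) and Mlxipl 0.19 (0.428). Fructose handling had 2 of 7 higher, also over the list alone (adjusted p = 0.00453, adjusted p = 0.119 with an estimated correlation), with Khk 1.40-fold higher. Glycolysis had 2 of 13 higher, also over the list alone (adjusted p = 0.0261, adjusted p = 0.232 with an estimated correlation), Gpi1 being 1.78-fold higher. Fatty acid synthesis had 4 of 17 higher and 0 lower, 9 and 0 over the list alone (adjusted p = 0.00323, adjusted p = 0.117 with an estimated correlation), with malic enzyme, Me1, 2.46-fold, Acly 2.11-fold and Acaca 1.81-fold higher. Fasn had a log2 fold change of 0.71 (adjusted p = 0.0851), Scd1 0.48 (0.455) and Srebf1 0.11 (0.912).

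Amino acid genes changed in both directions with glucose. The ATF4 and amino acid stress list had 6 of 15 higher and 0 lower, 8 and 0 over the list alone (adjusted p = 3.01e-07, adjusted p = 0.00418 with an estimated correlation). Urea cycle and amino acid breakdown had 8 of 20 lower and 0 higher, 18 and 0 over the list alone (adjusted p = 0.000118, adjusted p = 0.0384 with an estimated correlation), with Sds 1.69-fold, Ass1 1.44-fold and Cps1 1.43-fold lower. Pck2, a mitochondrial enzyme of the gluconeogenesis list, was 1.86-fold higher, although that list did not pass its test (adjusted p = 0.465). Xenobiotic genes had 3 of 11 lower, 8 over the list alone (adjusted p = 0.00026, adjusted p = 0.0384 with an estimated correlation), with the P450 reductase Por 1.41-fold lower. Periportal markers had 4 of 10 lower and 1 higher, 6 and 1 over the list alone (adjusted p = 0.00323, adjusted p = 0.119 with an estimated correlation). Most of these markers are also in the amino acid breakdown list. Pericentral markers had 1 of 10 lower, 6 over the list alone (adjusted p = 0.00491, adjusted p = 0.119 with an estimated correlation). Bile acid genes had none of 12 called, 4 lower over the list alone (adjusted p = 0.00297, adjusted p = 0.117 with an estimated correlation), Cyp7a1 having a log2 fold change of -1.28 (adjusted p = 0.107). Insulin and growth hormone genes had 2 of 11 lower, 4 over the list alone (adjusted p = 0.00584, adjusted p = 0.131 with an estimated correlation), with Igfbp2 1.36-fold lower. NRF2 targets had 0 of 8 called, 2 higher over the list alone (adjusted p = 0.0341, adjusted p = 0.216 with an estimated correlation). The other 24 lists did not pass, among them PPARA targets (adjusted p = 0.703), cholesterol synthesis (0.565) and endoplasmic reticulum chaperones (0.166). The medians of the 12 lists that passed had the same sign in all 3 slides, and 10 kept their call with any 1 array left out. The NRF2 list lost its call in 11 of 30 alternative settings, and Sds and Cabp4 lost theirs when the probes of a gene were averaged.

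Fructose in the drinking water asks the same of the other sugar. Fgf21 was 10.9-fold higher than on water, at a log2 level of 0.60 ± 0.86 (SD, n = 6; adjusted p = 0.00148). Psat1 was 6.58-fold and Phgdh 4.36-fold higher (2.72 ± 0.31 and 2.12 ± 0.35 in log2, SE), Fut1 at least 4.22-fold higher, Cabp2 4.67-fold higher with 5 of 6 water arrays above background, and Plcxd1 2.95-fold higher. Agxt was 3.17-fold lower (-1.66 ± 0.24; adjusted p = 0.00148), Sspo 2.55-fold, the interferon-induced gene Ifi47 1.73-fold, the DNA methyltransferase Dnmt3b 1.72-fold, Dcxr 1.68-fold and the chaperone Hspa5 1.66-fold lower. In all, 120 genes were higher and 91 lower, 25 and 10 of them by at least 2-fold. The share of calls that were higher was 56.9%, and it depended on the scaling, from 49.2% with normexp correction (268 higher and 277 lower) to 67.4% when arrays were scaled by their median (95 higher and 46 lower). The groups did not overlap in 423 genes, 1.77% of those tested, where chance gives 0.216%. With slide as a block the counts were 110 and 83, and within slides 1, 2 and 3 they were 0, 0 and 3 higher and 0, 0 and 1 lower. All 31 called genes named by the rule kept their sign in all 3 slides, and 20 kept the call with any 1 array left out. The genes given here as higher or lower with fructose were chosen from those 20, so their kept calls are no further support. Single arrays moved the counts: without fed_fructose replicate 4 they were 250 higher and 163 lower, and without fed_water replicate 4 they were 46 and 19.

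With fructose 10 lists passed the test. The carbohydrate response list had 1 of 13 higher, 6 over the list alone (adjusted p = 0.00153, adjusted p = 0.114 with an estimated correlation), while Pklr had a log2 fold change of 0.69 (adjusted p = 0.0675) and Txnip 0.40 (0.243). Fructose handling had 1 of 7 higher, 3 over the list alone (adjusted p = 0.0201, adjusted p = 0.249 with an estimated correlation), with Khk 1.37-fold higher. Glycolysis had 2 of 13 higher, 4 over the list alone (adjusted p = 0.00996, adjusted p = 0.216 with an estimated correlation), with Gpi1 1.92-fold higher. Fatty acid synthesis had 4 of 17 higher, 11 over the list alone (adjusted p = 0.00446, adjusted p = 0.119 with an estimated correlation), with Me1 2.69-fold and Acaca 1.67-fold higher. The ATF4 list had 3 of 15 higher, 7 over the list alone (adjusted p = 0.00125, adjusted p = 0.117 with an estimated correlation), Nupr1 being 2.13-fold higher by its brighter probe, with the other at a log2 fold change of 0.03. Urea cycle and amino acid breakdown had 3 of 20 lower, 10 over the list alone (adjusted p = 0.00431, adjusted p = 0.141 with an estimated correlation), with Ass1 1.33-fold lower. Endoplasmic reticulum chaperones had 4 of 18 lower, 14 over the list alone (adjusted p = 0.00293, adjusted p = 0.119 with an estimated correlation). Insulin and growth hormone genes had 0 of 11 called, 3 lower over the list alone (adjusted p = 0.0265, adjusted p = 0.284 with an estimated correlation). NRF2 targets had 0 of 8 called, 3 higher over the list alone (adjusted p = 0.0306, adjusted p = 0.249 with an estimated correlation). Periportal markers had 1 of 10 lower, 3 over the list alone (adjusted p = 0.0236, adjusted p = 0.287 with an estimated correlation), and most of them are also in the amino acid breakdown list. The clock list did not pass (adjusted p = 0.303), with Nr1d1, a clock repressor, 2.30-fold higher. The other 25 lists did not pass either. Of the 10 lists that passed, 9 had medians of the same sign in all 3 slides, the exception being glycolysis, and 6 kept their call with any 1 array left out. Fitted with only the 12 arrays compared, Hspa5, Dnmt3b, Dcxr, Acaca, Ass1, Nupr1 and Nr1d1 lost the call, and over 30 alternative settings the NRF2 and insulin lists each lost theirs in 11.

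**Figure D3:**
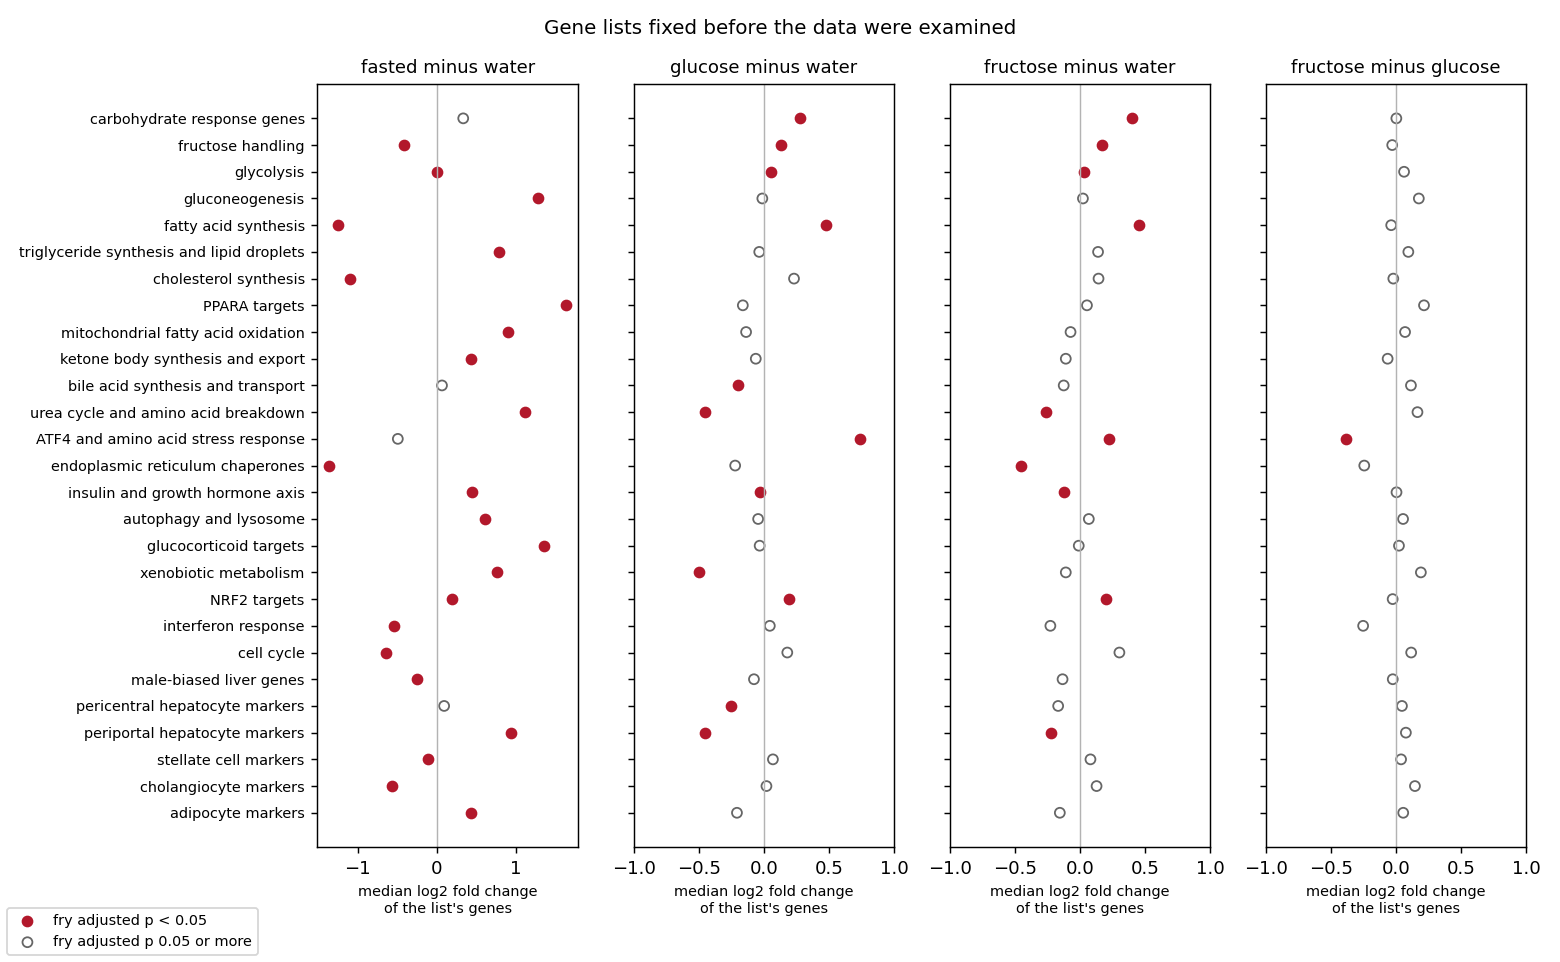
Median log2 fold change of the genes of each list that passed the test in at least 1 comparison, with filled points where the fry adjusted p was under 0.05. The chaperone list stands at -1.36 with fasting, -0.22 with glucose and -0.45 with fructose.

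Fructose against glucose asks whether the sugars differ. No gene was called by limma in either direction. At an unadjusted p under 0.05, 942 genes were higher and 927 lower with fructose, 1869 in all where 1198.3 would be expected by chance, and the lowest adjusted p was 0.0672, for Csrp2, a gene chosen after its values were seen. The median half-width of the 95% interval was 0.236 on the log2 scale and the 90th percentile 0.580. Fgf21 had a log2 fold change of -0.96, with an interval from -2.01 to 0.08 (adjusted p = 0.673), Psat1 -0.91 (interval -1.55 to -0.27; adjusted p = 0.495), Phgdh -1.24 (interval -1.97 to -0.51; adjusted p = 0.447), Pklr -0.29 (adjusted p = 0.735), Khk -0.03 (0.966) and Cyp7a1 0.98 (0.55). The ATF4 and amino acid stress list was lower with fructose than with glucose, with 0 of 15 members called, 5 lower over the list alone and a median of -0.38 (adjusted p = 0.00285, adjusted p = 0.041 with an estimated correlation). Its medians within slides were -0.19, -0.20 and -0.62, and the call was lost within slides 1 and 2. The other 35 lists did not pass, xenobiotic metabolism coming closest (adjusted p = 0.0513), but this depended on the setting. Quantile normalization and the series table each called 3 more lists as higher with fructose, xenobiotic metabolism (adjusted p = 0.022 and 0.0221), bile acids (0.0474 and 0.0371) and gluconeogenesis (0.0461 and 0.0482), and camera with the preset correlation called 9 more, while camera with an estimated correlation called none more. With slide as a block no gene was called. Array weights, normexp correction and some other settings called a few genes, as listed in the part on processing.

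Both sugars were compared with the same water mice. They shared 62 calls of the same sign, 39 higher and 23 lower, and 0 of opposite sign. Several of the 39 are features named only by an accession or a Gm number, with changes close to those of Psat1 and Phgdh, and whether they repeat the signal of 1 transcript was not tested, so the number of separate genes may be lower. Independent lists would share 0.874 of the same sign, and simulated unchanged groups against the shared control shared 0.01 on average and 1 at most. Unchanged groups hold no changed gene to call, so that count is no baseline for the 62. Across all genes the log2 fold changes of the 2 sugars correlated at 0.6825. The shared control alone gave 0.501 in the simulated unchanged groups, and split water arrays gave a median of 0.307. With the 6 water arrays split 3 and 3 between the sugars, the shared count had a median of 11, from 6 to 19, but these fits called medians of only 50 genes with glucose and 22.5 with fructose, so the fall from 62 does not measure the shared control alone. Fasting and glucose called 110 genes in opposite directions, 63 higher with fasting and lower with glucose and 47 the reverse, and 41 in the same direction, where 42.4 of each would be expected. Split water arrays gave a median of 26.5 opposite calls, from 13 to 54, and 6 of the same sign. Fasting and fructose called 62 genes in opposite directions and 75 in the same direction, where 44.8 and 45.1 would be expected, and split arrays gave medians of 10 and 6.5. These counts depended on single arrays. With 1 array left out, opposite calls ran from 25 (without fed_fructose replicate 6) to 149 (without fasted replicate 2) for fructose. For glucose they ran from 62 (without fed_water replicate 5) to 155 (without fasted replicate 2). Calls of fasting and a sugar in the same direction were not counted in these fits, so which kind was more frequent there is not known. Calls shared by the sugars ran from 35 (without fed_fructose replicate 6 or fed_water replicate 4) to 84 (without fed_fructose replicate 2). Phgdh, Psat1, Me1 and Khk rose with both sugars, Agxt, Dcxr and Ass1 fell with both sugars and rose with fasting, and Fgf21 rose in all 3 comparisons.

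**Figure D4:**
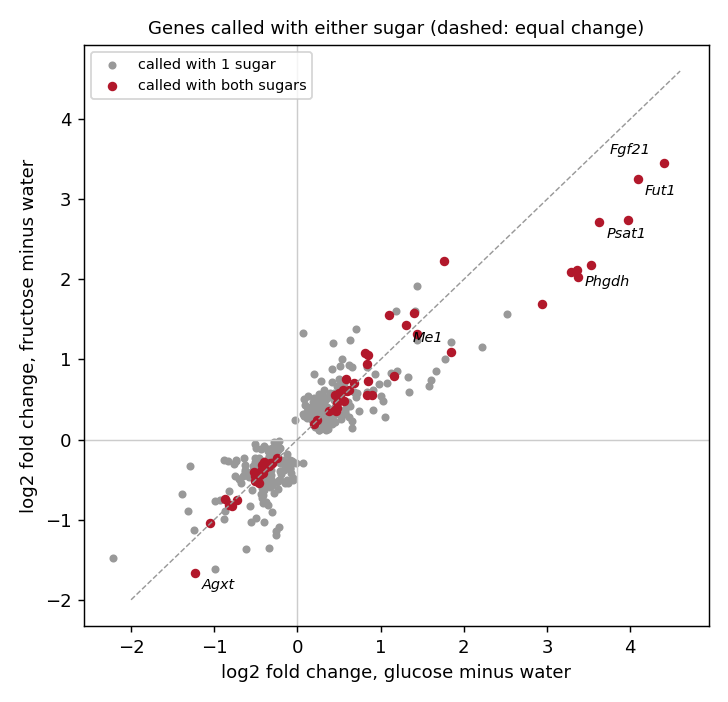
Log2 fold change with fructose against that with glucose for genes called with at least 1 sugar, with genes called with both in red and equal change as a dashed line. All 62 genes called with both lie in the quadrants of equal sign, and Fut1 is drawn at its fitted value although its water arrays lie under background.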

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

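Chosen after the results were seen were the tests of slide, partial fasting and endoplasmic reticulum stress in the ATF4 pattern and all tests of the Fgf21 and Cidec patterns, while the splits of the arrays and the added gene lists of the ATF4 pattern were set beforehand.

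With both sugars the ATF4 and amino acid stress list passed its test as higher and amino acid breakdown as lower. With glucose 6 of 15 and 8 of 20 genes were called, and both lists also passed camera with an estimated correlation. With fructose 3 of 15 and 3 of 20 were called, and neither passed camera that way (adjusted p = 0.117 and 0.141). All 12 medians of these lists within slides (2 lists, 2 sugars, 3 slides) kept the pooled sign, so no single slide carried the pattern. Each slide held 2 arrays of every group, so the design had already balanced slide between the groups. Partial fasting in mice that ate less chow would not lower amino acid breakdown if it acted as the 24-hour fast did, since that list had a median of 1.12 in fasted mice (adjusted p = 1.87e-10). For the rise of the ATF4 list it stays open, since that list went both ways in fasted mice, with a median of -0.490 (adjusted p = 0.316). Endoplasmic reticulum stress would raise chaperones, of which at most 1 of 18 lay above 0 with either sugar. Lists written before their values were seen moved with the pattern: aminoacyl-tRNA synthetases and amino acid transporters had a median of at least 0.125 with each sugar (fry adjusted p = 3.37e-05 with glucose and 0.0121 with fructose), and 30 other amino acid breakdown genes a median of at most -0.218 (adjusted p = 0.00466 and 0.0198). A response to lower protein intake in mice that drank sugar may fit these values and stays open, since food intake is not given and no test of it was possible.

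Fgf21 was higher with fasting and with both sugars. PPARA activation by the sugars would raise the other PPARA targets, whose median without Fgf21 was at most 0.0236 with either sugar against 1.63 with fasting. The carbohydrate response genes without Fgf21 had a median of at least 0.264 with each sugar (fry adjusted p = 0.00197 with glucose and 0.0021 with fructose), which is consistent with a carbohydrate response as a candidate source of the rise. The evidence is weaker with fructose, where 0 of these 12 genes were called. There neither the whole carbohydrate list (adjusted p = 0.114) nor the ATF4 list (0.117) passed camera with an estimated correlation. ATF4, for which Fgf21 is a known target, stays open as well.

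Cidec and Plin4, lipid droplet genes that adipocytes also express, were higher in fasted livers. Adipose tissue in the samples would raise adipocyte markers too, by an amount that depends on each gene's level in adipose tissue and in liver. Cidec rose by 4.56 more on the log2 scale than the median of the 6 markers, of which Adipoq and Fabp4 were called. Levels in adipose tissue were not measured, so this difference cannot decide whether adipose tissue added to the rise of Cidec. The markers' own rise depends on dim probes, since their median was -0.14 and their call was lost with the strict filter. Adipose tissue as a source of the rise of Cidec, Plin4 or Adipoq stays open, and a change within hepatocytes is a hypothesis that was not tested.

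Of 100 splits of the 12 arrays into 6 and 6, the real one included, only the real split gave as many called genes for fasting (10211, highest other 6154), glucose (199, highest other 1) and fructose (211, highest other 21). The 100 were drawn from 462 distinct splits, so counts this large are unlikely by chance there. A total count says nothing about any single gene. The fasting split with 6154 calls kept 5 of the 6 fasted arrays together. Lists adjusted within each comparison gave 25 for fasting (highest other 18), 12 for glucose (highest other 2) and 10 for fructose (highest other 2), and again 1 of 100 splits, the real one, reached each count. For fructose against glucose the count of genes tells nothing, since all 100 splits reach a real count of 0 (highest other 2). As many lists as the real 1, whichever list it was, came from 10 of 100 splits (highest other 2), so the number of lists called there does not exclude chance. The splits did not test the ATF4 list by itself.

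Single arrays far from the other 5 of their group were sought with Dixon's test in 404 groups of values, for 98 genes and some array measures, and 39 (9.65%) lay over its 95% critical value, where chance marks about 1 in 20. Fasted replicate 2 had 7 of them: Acaca (0.723), Cidec (0.692), Cyp8b1 (0.713), Elovl6 (0.699), Fasn (0.737) and Fut1 (0.741) were lowest there and Trib3 (0.776) highest, and its array weight was the lowest of the 24, at 0.344. Fasted replicate 6 was lowest for Cyp2c55 (0.626) and Khk (0.776) and highest for Fabp4 (0.68) and Slco1a1 (0.768). Aox3 was highest in fasted replicate 1 (0.663) and Cyp1a2 lowest in fasted replicate 4 (0.753). With fructose, Pdk4 (0.819) and the number of outlier spots (0.738) stood out in replicate 2, Cyp8b1 (0.694) in replicate 3, Cyp2c55 (0.69), Cyp4a10 (0.638) and Cyp4a31 (0.646) in replicate 4, Adipoq (0.64) and Aldh1l2 (0.78) in replicate 5 and Txnip (0.725) in replicate 6. With glucose, Got1 (0.738), Psph (0.627) and Serpina4-ps1 (0.705) stood out in replicate 1, Cyp2c55 (0.643) in replicate 2, Cyp4a14 (0.777), Pnpla5 (0.72), Sds (0.743) and Thrsp (0.729) in replicate 3, and Cyp1a2 (0.647) in replicate 4. On water, Arntl (0.628) and Txnip (0.629) stood out in replicate 1, Irs2 (0.672) in replicate 2, Gcdh (0.759), Hal (0.737), Phgdh (0.688) and Tg (0.731) in replicate 3 and Sds (0.636) in replicate 5.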

How the results depend on the processing

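No called gene named by the rule and no called list took the opposite test direction under any alternative. Called genes outside the rule were not checked for this. All alternatives were set before the data were examined. List medians did cross 0 for glycolysis with fasting (0.005, down to -0.04 with the series table), adipocyte markers with fasting (0.43, against -0.14 with the strict filter on dim probes, where the call was lost), and, within single slides, male-biased genes, stellate markers and glycolysis with fructose. Signal over background limits the values of dim genes, and the causes of the changes below were not tested, except that within a slide 2 arrays meet 2 and that stricter thresholds call fewer genes by construction. Counts moved beyond 1.5 times as follows. Quantile normalization gave 203 genes higher with fructose. Median scaling gave 46 lower with fructose and 1 higher in fructose against glucose. Normexp correction with the 75th percentile gave 268 higher and 277 lower with fructose, 1 higher and 3 lower in fructose against glucose, 104 shared by the sugars and 148 opposite between fasting and fructose. Normexp correction with quantile normalization gave 187 higher and 156 lower with glucose, 321 and 179 with fructose, 2 and 3 in fructose against glucose, 115 shared, 177 opposite for glucose and 161 for fructose. The deposited series table gave 156 higher with glucose, 239 higher with fructose and 114 opposite for fructose. No filter on dim probes gave 64 higher and 56 lower with glucose, 56 and 23 with fructose, 1 higher in fructose against glucose, 40 shared, 70 opposite for glucose and 31 for fructose. The strict filter and the mean of all probes each gave 1 higher in fructose against glucose, and the latter 1 lower. Only the arrays compared gave 184 lower with glucose, 58 higher and 16 lower with fructose, 33 shared and 27 opposite for fructose. Trended and robust variances gave 185 lower with glucose, 191 higher and 159 lower with fructose, 1 and 1 in fructose against glucose, 96 shared, 176 opposite for glucose and 111 for fructose. Array weights gave 213 higher and 311 lower with glucose, 213 and 188 with fructose, 1 and 5 in fructose against glucose, 131 shared, 273 opposite for glucose and 132 for fructose.

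Within slides 1, 2 and 3, fasting gave 2795, 3211 and 2974 higher and 2705, 3355 and 2485 lower, glucose 2, 0 and 36 higher and 0, 0 and 5 lower, and fructose 0, 0 and 3 higher and 0, 0 and 1 lower. The sugars shared 0, 0 and 4, opposite calls were 0, 0 and 11 for glucose and 0, 0 and 2 for fructose, and 23, 23 and 26 lists were called against 46 over all arrays. An adjusted p under 0.01 gave 37 higher and 19 lower with glucose, 22 and 6 with fructose, 18 shared, 30 opposite for glucose and 11 for fructose. A change of at least 2-fold gave 963 and 873 with fasting, 32 and 7 with glucose, 25 and 10 with fructose, 17 shared, 16 opposite for glucose and 8 for fructose. Camera called 54 lists with the preset correlation and 6 with an estimated correlation. In fructose against glucose, where 1 list was called, more were called under some settings: xenobiotic metabolism, higher with fructose, with quantile normalization (adjusted p = 0.022), median scaling (0.046), normexp correction with the 75th percentile (0.0378) or quantiles (0.0186), the series table (0.0221), the mean of all probes (0.0419), array weights (0.0371) and slide as a block (0.0444), bile acids with normexp and quantiles (0.0457), and bile acids and gluconeogenesis with quantile normalization and the series table, autophagy and lysosome with only the arrays compared (0.0421), interferon response (0.00394) and Kupffer cell markers (0.0276), both lower, within slide 1, and cell cycle, higher, within slide 3 (0.019). Single arrays left out also added xenobiotic metabolism (without fed_fructose replicates 1 or 6 or fed_glucose replicates 3 or 6), chaperones (without fed_fructose replicate 5) and Kupffer cell markers (without fed_glucose replicate 6). Camera with the preset correlation called 9 more, among them chaperones, interferon response and Kupffer cell markers as lower and amino acid breakdown and PPARA targets as higher with fructose. With the replicate block the counts were 5196 and 4972 for fasting, 88 and 82 for glucose, 102 and 65 for fructose, 0 and 0 for fructose against glucose and 47 lists.

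With each array left out in turn, fasting gave 4871 to 5293 higher and 4657 to 5015 lower, glucose 54 to 87 higher and 46 to 85 lower, fructose 46 to 250 higher and 19 to 163 lower, and fructose against glucose 0 to 1 higher and 0 to 2 lower. The sugars shared 35 to 84, opposite calls were 62 to 155 for glucose and 25 to 149 for fructose, and 39 to 51 lists were called. The lowest and highest values came without fed_glucose replicate 1 or fed_water replicate 4 (54) and fed_water replicate 5 (46) for glucose, without fed_water replicate 4 (46 and 19), fed_fructose replicate 1 (19) and fed_fructose replicate 4 (250 and 163) for fructose, and without fasted replicate 2 (155 and 149) for the opposite calls. Leaving out an array moved the count beyond 1.5 times in 3 of 12 cases for genes higher and 10 of 12 for genes lower with glucose, and in 7 and 9 of 12 with fructose.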

Other observations

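All genes and lists described in this part were chosen after their values were seen, apart from the 2 added lists. Some of the 62 genes that both sugars moved alike are given here singly, and no group of them was tested. Transketolase, Tkt, was 1.51-fold higher with glucose and 1.52-fold with fructose (adjusted p = 0.00229 and 0.00386), the amino acid transporter Slc7a7 1.78-fold and 1.47-fold higher, and the stress transcription factor Atf5 2.23-fold and 1.74-fold higher. Slc38a4, another amino acid transporter, was lower, with log2 fold changes of -0.40 and -0.28. With fasting Atf5 was 2.43-fold higher, Tkt 2.27-fold lower and Slc7a7 1.26-fold lower. Of 2 single enzymes of amino acid breakdown, Ivd was 1.42-fold and 1.43-fold lower (adjusted p = 0.0081 and 0.01), and Gcdh 1.34-fold lower with each. Aox3, an aldehyde oxidase, was 1.77-fold lower with each.

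The added lists also moved with fasting. Of 19 aminoacyl-tRNA synthetases and amino acid transporters 3 were higher and 8 lower (fry adjusted p = 0.002, over 8 tests), against 6 higher and 0 lower with glucose and 1 higher with fructose. In fructose against glucose 17 of the 19 lay below 0 and 0 were called (fry adjusted p = 0.0114). Of 30 other amino acid breakdown genes 21 were higher and 3 lower with fasting (fry adjusted p = 2.91e-05), against 4 lower with glucose and 0 called with fructose.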
